A study of Mus musculus with 14 samples.

How the data were processed

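Total RNA of 12 osteosarcomas, 1 tumour labelled rhabdomyosarcoma and the cultured mc3T3 line had been extracted with a silica column kit, biotin-labelled by the array maker's usual procedure and hybridised to 14 arrays, per the labels' protocols. The series' values were read from a single table of 45101 probe sets by 14 arrays, of which 64 are control probe sets. The deposited values are the array signal (intensity) of each probe set on a linear scale; the software was GCOS, per the submitters' processing notes, its version not given in the sources used here. From the values, the mean of each array after dropping the highest and lowest 2% of probe sets was 500.0, so the arrays had been scaled to a common target before deposit. The background step and the probe-level summary are not given in the sources used here, and no detection calls were used, so a low signal could not be told from background. The number of arrays limits the precision.

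Samples were grouped by their titles, because the description field names mc3T3 for every sample. The labels give no replicate numbers, so tumours were numbered in accession order, which only names them. The labels do not say whether the 12 osteosarcomas came from separate animals; p-values therefore measure the spread between these samples. The highest correlation between 2 arrays was 0.954 and 0 columns were identical, so all arrays were kept.

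Each array was rescaled to a trimmed mean of 500, and log2(signal + 30) was analysed. A difference is therefore on the log2(signal + 30) scale, which understates the change of low genes. Probe sets with a signal of at least 200 on at least 1 array were tested, 22479 in all. Gene symbols came from the platform annotation, updated through the Entrez identifier for 34741 probe sets with a gene table of assembly GRCm38.p6; 34945 probe sets had 1 symbol, 932 several genes and 9160 were unnamed here. A gene was represented by its brightest tested probe set (highest mean over the 14 arrays), giving 11815 genes; 0 genes had probe sets called in opposite directions. That gene table was otherwise used only for which genes neighbour each other.

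Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg) in a model of 3 groups. Probe sets and genes were fitted separately. Probe set counts were adjusted over the 22479 probe sets tested, and gene results over the 11815 genes. The residual spread came from the 12 osteosarcomas (11 degrees of freedom, 3.56 prior degrees of freedom). A call needed an adjusted p under 0.05 and a change of at least 1 on the log2 scale. The median change over all genes was -0.02 for osteosarcoma against mc3T3 and 0.05 for the tumour labelled rhabdomyosarcoma against osteosarcoma. As a scale for calls from a lone array, each osteosarcoma was also set against the other 11. Simulated data drew each gene on every array independently from a normal distribution with its osteosarcoma mean and SD, with 200 of 11815 genes changed. They assume that a lone array varies as an osteosarcoma does and hold no correlation between genes. Their false calls therefore do not give the rate on the real arrays. In these data the comparison with mc3T3 recovered 8% of genes changed by 1 on the log2 scale, 48% by 2, 86% by 4 and 92% by 6, with 6 false calls. The comparison of the tumour labelled rhabdomyosarcoma recovered 4% of genes changed by 1, 60.0% by 2, 92% by 4 and 100% by 6, with 7 false calls.

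In all, 23 gene lists were written before the data were examined, and each was tested with camera at a preset correlation of 0.01, adjusted over the lists; 10 lists passed for osteosarcoma against mc3T3 and 9 for the tumour labelled rhabdomyosarcoma against osteosarcoma. With a correlation estimated from the residuals, 0 and 1 passed; the 1 was the osteoblast list. Mdm2, Perp and Mmp8 each stand in a pair of lists. Of 485 list members, 42 had no probe set named in the tables used and are not analysed here. The planned relation of p53 targets with the Trp53 level is among what was left out, so that 5 of 6 planned relations were run. Where both groups hold 1 array, a list's median difference was placed among 10000 random lists of the same size matched on mean expression. Correlations across tumours used 100000 permutations, or all 720 orders for 6 tumours.

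The rule for named genes was fixed before the data were examined. It took the 8 highest and 8 lowest called genes per comparison with all 12 osteosarcomas on 1 side, up to 4 called members per list, the osteosarcoma and p53 pathway genes, the chromosome 9 genes, the 10 genes with the largest SD and a short fixed set of bone and muscle genes. Neighbouring genes were scanned on 9772 genes with an osteosarcoma mean of at least 200, in running windows of 11 genes. A run was a stretch of windows whose median lay at least 1 on the log2 scale above the median osteosarcoma, and its length was compared with 100 shuffles of the gene order. The scan was not planned, and its settings were chosen after earlier looks at all tested genes and at genes above a minimum mean signal, in which chromosome ends gave spurious runs. Genes at the very end of a chromosome cannot be the centre of a window. In 10 simulated arrays of 6000 genes each, a planted block of 25 genes was found in 10 of 10 at 1, 2 or 3 on the log2 scale and in 0 of 10 at 0. The median run was 7 windows at 1, 23 at 2 and 25 at 3, so the extent of a block was understated at 1. The simulated genes were independent, so the 0 of 10 does not give the rate of such runs on real arrays. Alternatives were no rescaling, quantile normalization, pseudocounts of 10 and 100, no signal filter and one at 500, an intensity trend, the mean of a gene's probe sets, the m tumours alone, an estimated correlation in camera, and leaving out each osteosarcoma. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.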

Results

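RNA from 14 mouse samples was hybridised to Affymetrix expression arrays. Of these, 12 were osteosarcomas, bone tumours whose cells lay down bone matrix, and 1 was a tumour labelled rhabdomyosarcoma, a sarcoma of the skeletal muscle lineage. The tumours came from p53+/- mice, heterozygous for the p53 tumour suppressor. The remaining array held RNA of mc3T3, a non-tumorigenic mouse osteoblast line grown in culture and used as the control. The median signal of an array was between 67.1 and 111 units, and between 33.8% and 40.4% of probe sets reached a signal of 200. The 3' to 5' signal ratio of beta-actin, a measure of RNA integrity, was 1.42 to 2.13 in the osteosarcomas, 1.24 in the tumour labelled rhabdomyosarcoma and 1.32 in mc3T3. Each osteosarcoma correlated with the mean of the other osteosarcomas across probe sets at r = 0.956 to 0.974, against 0.940 for the tumour labelled rhabdomyosarcoma and 0.893 for mc3T3. These correlations are across probe sets, which are not independent replicates.

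The osteosarcomas were first compared with the cultured osteoblast line, the control that the design names. This comparison sets tumour samples against a cultured line of a single cell type. A difference therefore cannot be read as a change within tumour cells, and the cell types present were not separated. The largest increases in the tumours were those of Ibsp and Acp5. Ibsp, which encodes bone sialoprotein, had a mean signal of 36507 ± 5607 (SD, n = 12) against 37.4 in mc3T3. The difference was 9.07 ± 0.28 on the log2 scale (SE; adjusted p = 8.35e-11). Acp5, the tartrate-resistant acid phosphatase of osteoclasts, had a mean signal of 37863 ± 9100.4 against 41.3, a difference of 9.02 ± 0.38. Pappa2, a protease of insulin-like growth factor binding proteins, went the other way, with 52.8 ± 29.0 in the tumours against 23850.2 in mc3T3. Its difference was -8.26 ± 0.53 (adjusted p = 2.10e-07). The 8 largest increases also held Gpx3 (8.78 ± 0.84), an extracellular glutathione peroxidase, and Car3 (8.73 ± 0.71), a carbonic anhydrase of muscle and fat. Apoe (8.58 ± 0.68), C1qb (8.03 ± 0.75) and Rpl39l (7.95 ± 0.87) were among them too. Ptgis, which makes prostacyclin, was the other gene of the 8, with a mean signal of 11233 ± 4302 against 11. The 8 largest decreases included the neutrophil chemokine Cxcl5 (-6.01 ± 1.11), the neurturin receptor Gfra2 (-5.90 ± 0.83), Sned1 (-5.67 ± 0.95), Ccn3 (-5.62 ± 0.99), Vgll3 (-5.30 ± 1.11), Mab21l1 (-5.30 ± 0.69) and the smooth muscle actin Actg2 (-5.19 ± 1.27).

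Of the osteoblast differentiation and bone matrix list, 10 of 23 measured genes rose, 2 fell and 11 did not pass. Dmp1 (6.42 ± 1.00) and Phex (5.68 ± 1.42), regulators of mineralisation, and Col11a2 (5.44 ± 0.72) rose most after Ibsp. The homeobox gene Msx2 (-2.97 ± 0.60) and the osteoblast cadherin Cdh11 (-1.99 ± 0.36) fell. The list as a whole was higher (camera adjusted p = 0.00147; adjusted p = 0.229 with an estimated correlation). Alpl, the tissue-nonspecific alkaline phosphatase, rose by 2.48 ± 0.36. Sp7, an osteoblast transcription factor, differed by 0.53 ± 0.52 and did not pass (adjusted p = 0.544). Of the osteoclast list, 16 of 18 genes rose and none fell. This list passed (camera adjusted p = 2.94e-18; adjusted p = 0.142 with an estimated correlation). Besides Acp5 it was led by the proton pump subunit Atp6v0d2 (6.56 ± 0.73), Car2 (6.29 ± 1.11) and the fusion protein Ocstamp (6.12 ± 0.98). Ctsk, the collagen-degrading protease of osteoclasts, rose by 3.46 ± 0.34.

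Of the macrophage and monocyte list, 20 of 22 genes rose and none fell, with a median difference of 6.24 on the log2 scale. It passed as a whole (camera adjusted p = 3.29e-27; adjusted p = 0.109 with an estimated correlation). C1qb, C1qa (7.81 ± 0.81), Laptm5 (7.69 ± 0.49) and Ctss (7.61 ± 0.67) led this group. Of the endothelial list, 14 of 20 genes rose and none fell. The endothelial list passed as a whole (camera adjusted p = 2.17e-12; adjusted p = 0.142 with an estimated correlation). Esam (5.28 ± 0.51), Emcn (4.86 ± 0.51), Mmrn2 (4.54 ± 0.55) and Pecam1 (3.92 ± 0.50) were among these genes. Of the MHC class II presentation list, 6 of 8 genes rose (camera adjusted p = 4.69e-05; adjusted p = 0.229 with an estimated correlation). H2-Aa (7.65 ± 1.14), H2-Eb1 (6.05 ± 1.37) and H2-Ab1 (5.95 ± 1.16) led them. Of the adipocyte list, 4 of 9 genes rose (camera adjusted p = 2.90e-05; adjusted p = 0.142 with an estimated correlation). They included Car3, the fatty acid carrier Fabp4 (7.52 ± 0.61) and the lipase Lpl (6.97 ± 0.91).

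Of the contractile and adherent-culture (YAP/SRF) genes, 6 of 19 fell and 2 rose. The list was lower as a whole (camera adjusted p = 0.000948; adjusted p = 0.229 with an estimated correlation). Actg2 and the focal adhesion gene Tgfb1i1 (-3.40 ± 0.50) fell. Ccn2 (3.94 ± 0.68), a matrix protein that YAP induces, and Filip1l (2.08 ± 0.38) rose. Of the cholesterol synthesis list, 2 of 15 genes fell, Mvk (-2.07 ± 0.42) and Msmo1 (-1.37 ± 0.37). The list passed (camera adjusted p = 0.000948; adjusted p = 0.142 with an estimated correlation). Msmo1 did not pass with the tumours whose identifiers start with m alone (adjusted p = 0.0706, against 0.0175 to 0.0706 over all its alternatives). The list of myogenic regulators and embryonic muscle passed (camera adjusted p = 0.00899; adjusted p = 0.707 with an estimated correlation). It had 1 of 18 genes called, the muscle cadherin Cdh15 (3.34 ± 0.63). The mature skeletal muscle list passed with 0 of 28 genes called by limma (camera adjusted p = 0.00899; adjusted p = 0.722 with an estimated correlation). Its mean level was 9.05 ± 2.15 (SD, n = 12) in the osteosarcomas and 6.28 in mc3T3. Osteosarcomas 6 and 9 stood apart in both muscle lists (13.27 and 12.27 for mature muscle, 10.17 and 9.96 for the myogenic list), while the mature muscle level of osteosarcomas 4 (6.42) and 11 (6.51) lay near that of mc3T3.

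The other 13 lists did not pass as a whole. Of 25 p53 target genes, 1 rose and 3 fell (camera adjusted p = 0.0543). Pmaip1 (3.13 ± 0.52), which promotes apoptosis, rose. Psrc1 (-3.43 ± 0.79), Dcxr (-2.76 ± 0.57) and the death receptor Fas (-2.65 ± 0.67) fell. Of the osteosarcoma and p53 pathway genes, 4 of 23 rose and 1 fell (camera adjusted p = 0.371). These included the cell cycle inhibitors Cdkn2b (4.14 ± 1.03) and Cdkn2a (3.50 ± 1.09, adjusted p = 0.0461), the transcription factor Fos (3.10 ± 0.56) and, as the decrease, the p53 inhibitor Mdm4 (-1.95 ± 0.47). Without osteosarcoma 2, 3, 4, 5, 9, 10 or 12 in turn, Cdkn2a did not pass (adjusted p = 0.0541 to 0.0602), and over all its alternatives its adjusted p was 0.0144 to 0.111. The oncogenes and cell cycle genes Myc (-0.78 ± 0.33), Mycn (1.21 ± 1.01), Ccnd1 (0.51 ± 0.60), Cdk4 (-0.71 ± 0.46) and Rb1 (0.79 ± 0.36) did not pass. The p53 targets Mdm2 (0.00 ± 0.45) and Cdkn1a (1.34 ± 0.76) did not either.

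In the fibroblast and interstitial matrix list, 5 of 22 genes rose and 1 fell (camera adjusted p = 0.345). The median difference (-0.19) and the mean difference (0.51) of this list have opposite signs. The stromal protease Fap (6.82 ± 0.40), Col14a1 (4.14 ± 0.74) and Fbln1 (3.70 ± 0.59) rose, and the proteoglycan Ogn (-4.46 ± 0.80) fell. In the cartilage list 1 of 13 genes rose and 2 fell (camera adjusted p = 0.766). The collagen gene Col9a1, with 947 ± 616 against 1.8, rose. The chondrogenic factors Sox9 (-3.63 ± 0.77) and Sox5 (-2.92 ± 0.34) fell. The antiviral gene Rsad2 (3.78 ± 1.06) was the single gene of 21 called in the interferon response list (camera adjusted p = 0.988). This list had a median difference of -0.00 and a mean difference of 0.17. Lcn2 (-4.56 ± 1.25), an iron-binding protein of granules, was the single gene of 12 called in the neutrophil and granulocyte list (camera adjusted p = 0.172). Lcn2 did not pass with the m tumours alone (adjusted p = 0.0948, against 0.000658 to 0.0948 over all its alternatives). Mmp13, a collagenase, rose by 1.45 ± 0.34 and was the single gene of 19 called in the chromosome 9 MMP-Birc-Yap1 region list (camera adjusted p = 0.0707). The glycolytic enzyme Aldoa (1.80 ± 0.57, adjusted p = 0.0496) was the single gene of 17 called in the hypoxia and glycolysis list (camera adjusted p = 0.0801). Aldoa missed the threshold under 14 of 22 alternatives (adjusted p = 0.0189 to 0.0753 over all of them). Leaving out any of osteosarcomas 1 to 5 and 9 to 12 in turn was among these (0.0543 to 0.0662). No gene was called by limma in the lists of T and NK cell (12 measured, camera adjusted p = 0.490), B and plasma cell (5, 0.273), erythroid (9, 0.273), skin keratinocyte (7, 0.430) or cell cycle and mitosis genes (28, 0.330).

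**Figure D1:**
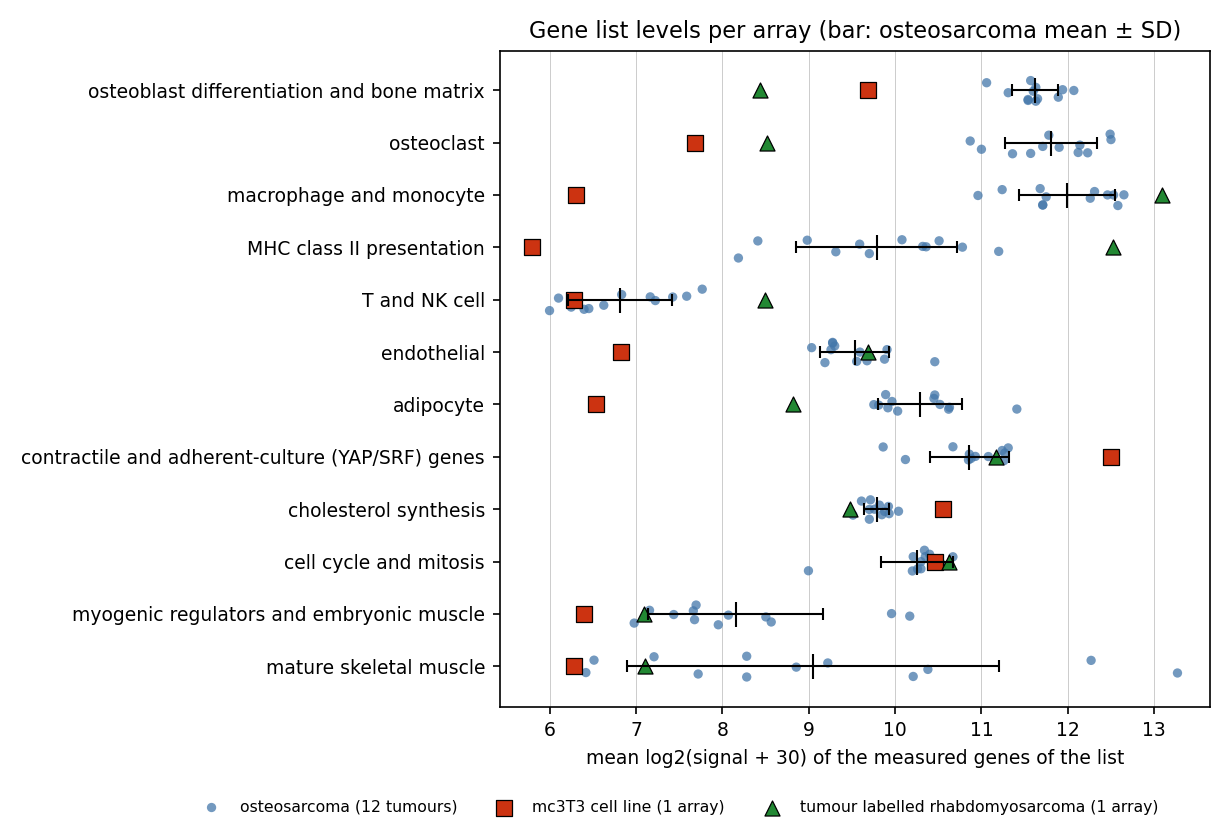
Mean level of 12 gene lists on each array, as the mean of log2(signal + 30) over the measured genes of a list (horizontal axis, log2 units). Dots are the 12 osteosarcomas, with a bar for their mean and SD, squares mc3T3 and triangles the tumour labelled rhabdomyosarcoma; the macrophage and monocyte level was 11.99 ± 0.56 in the osteosarcomas, 6.30 in mc3T3 and 13.09 in the tumour labelled rhabdomyosarcoma.

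Over all 11815 genes tested, 1015 rose and 541 fell in osteosarcoma at an adjusted p under 0.05 and a change of at least 1 on the log2 scale (limma, two-sided), with all 12 tumours on 1 side of the mc3T3 value for each of them. A call nearly entails this, because the spread it is judged by is that of the same 12 tumours, so it is no separate evidence. By probe set, 1571 rose and 951 fell out of 22479. Adjusted over the list alone, the genes called higher and lower were 10 and 2 for osteoblast differentiation and bone matrix, 18 and 0 for osteoclast, 22 and 0 for macrophage and monocyte, 14 and 0 for endothelial, 7 and 0 for MHC class II presentation, 6 and 0 for adipocyte, 2 and 8 for contractile and adherent-culture, 0 and 3 for cholesterol synthesis, 1 and 0 for myogenic and 0 and 0 for mature muscle genes. For the lists that did not pass, the counts adjusted over the list alone were 2 and 4 for p53 targets, 4 and 1 for osteosarcoma and p53 pathway, 6 and 1 for fibroblast, 2 and 2 for cartilage, 2 and 1 for neutrophil, 1 and 0 for B and plasma cell, 1 and 0 for the chromosome 9 region, and 0 and 0 for interferon, hypoxia, T and NK cell, erythroid, keratinocyte and cell cycle genes. With a single control array the test asks whether that array lies outside the tumours, and assumes that mc3T3 would vary as an osteosarcoma does. A single osteosarcoma set against the other 11 gave between 0 and 59 genes, the most in osteosarcoma 12. With quantile normalization the highest of these counts was 22.

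The tumour labelled rhabdomyosarcoma was then compared with the 12 osteosarcomas. Bone matrix genes were lower in it. Ibsp fell by 7.61 ± 0.28 on the log2 scale, to a signal of 155 (adjusted p = 1.03e-09). Alpl fell by 6.72 ± 0.36, to 54.0 (adjusted p = 5.27e-08), and Mmp13 fell by 6.52 ± 0.34, to 357. Panx3 (-6.65 ± 0.86), a channel protein of osteoblasts, and Ifitm5 (-6.44 ± 0.64), a membrane protein of mineralising osteoblasts, were among the 8 largest decreases. Dmp1 (-6.63 ± 1.00), Ptgis (-5.97 ± 0.58) and Ptprd (-5.96 ± 0.56) completed them. The largest increase was that of Crabp1, a retinoic acid binding protein, with a signal of 6197 against 19.3 ± 19.2 (7.06 ± 0.48; adjusted p = 6.55e-07). The chromatin protein Hmga2 (6.33 ± 0.84) and Igfbp6 (5.89 ± 0.94) came next. The stem cell transcription factor Sox2 had 1584 against 9.05 ± 8.21 (5.40 ± 0.33; adjusted p = 2.52e-07). Mmp3 (5.28 ± 1.16), Nxph1 (5.13 ± 0.48), Spon2 (5.11 ± 0.61) and AW551984 (5.02 ± 0.47) were the other 4 of the top 8. The muscle genes Myod1, Myog and Des did not pass. The myogenic factor Myod1 had a signal of 39.4 against 21.3 to 455 in the osteosarcomas and 23.8 in mc3T3. Its relative Myog had 65.9 against 11.7 to 530.2 and 58.9. The muscle filament gene Des had 88.6 against 100.5 to 7744 and 81.4.

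Of the osteoblast differentiation and bone matrix list, 14 of 23 genes fell and none rose, including Sp7 (-4.26 ± 0.52) and Col11a2 (-4.17 ± 0.72). This list passed in both forms of the test (camera adjusted p = 2.18e-24; adjusted p = 0.00312 with an estimated correlation). Of the osteoclast list, 10 of 18 genes fell (camera adjusted p = 5.92e-23; adjusted p = 0.101 with an estimated correlation). Ocstamp (-5.94 ± 0.98), Atp6v0d2 (-5.63 ± 0.73), Acp5 (-5.59 ± 0.38) and Dcstamp (-5.49 ± 0.92) led them. The MHC class II presentation list was higher (camera adjusted p = 1.64e-05; adjusted p = 0.337 with an estimated correlation), with 1 of 8 genes called, H2-DMa (3.62 ± 0.74). The interferon response list was higher (camera adjusted p = 4.79e-05; adjusted p = 0.638 with an estimated correlation), with 1 of 21 genes called, Gbp2 (3.48 ± 0.72). The T and NK cell list was higher (camera adjusted p = 0.000822; adjusted p = 0.354 with an estimated correlation), with 1 of 12 genes called, the chemokine Ccl5 (3.72 ± 0.85). The macrophage and monocyte list was higher with 0 of 22 genes called (camera adjusted p = 0.00130; adjusted p = 0.642 with an estimated correlation). The adipocyte list was lower (camera adjusted p = 0.00531; adjusted p = 0.337 with an estimated correlation), and 2 of 9 genes were called, Car3 (-5.85 ± 0.71) and Fabp4 (-3.36 ± 0.61). The mature skeletal muscle list was lower with 0 of 28 genes called (camera adjusted p = 0.00531; adjusted p = 0.7 with an estimated correlation). Its level of 7.10 lay within the range of the osteosarcomas (6.42 to 13.27), whose mean osteosarcomas 6 and 9 raise. Without these, an alternative chosen after the data had been seen, the list still passed as lower with the preset correlation. Lower too was the neutrophil and granulocyte list with 0 of 12 (camera adjusted p = 0.0169; adjusted p = 0.7 with an estimated correlation).

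The remaining 14 lists did not pass. Cdh15 (-4.50 ± 0.63) was the single gene of 18 called among myogenic regulators and embryonic muscle (camera adjusted p = 0.0517), and Sox5 (2.79 ± 0.34) the single gene of 13 in the cartilage list (0.0772). In the chromosome 9 region list Mmp3 rose and Mmp13 fell, of 19 genes (0.0860). Fap (-4.95 ± 0.40) and the matrix protein Tnc (-3.87 ± 0.65) fell among 22 fibroblast and interstitial matrix genes (0.692). Tnc did not pass when the mean of its probe sets was tested (adjusted p = 0.0665, against 0.000261 to 0.0665 over all its alternatives). The receptor tyrosine kinase gene Met (2.61 ± 0.66, adjusted p = 0.0450) was the single gene of 23 called in the osteosarcoma and p53 pathway list (0.0861). Met missed the threshold under 12 of 22 alternatives (adjusted p = 0.0127 to 0.0736 over all of them). Leaving out osteosarcoma 1, 3, 5, 6, 7, 9, 11 or 12 was among these (0.0506 to 0.0636). No gene was called by limma in the lists of B and plasma cell (camera adjusted p = 0.640), erythroid (0.273), endothelial (0.850), skin keratinocyte (0.479), contractile and adherent-culture (0.692), cell cycle and mitosis (0.0766), p53 target (0.479), hypoxia and glycolysis (0.0860) or cholesterol synthesis genes (0.0860).

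**Figure D2:**
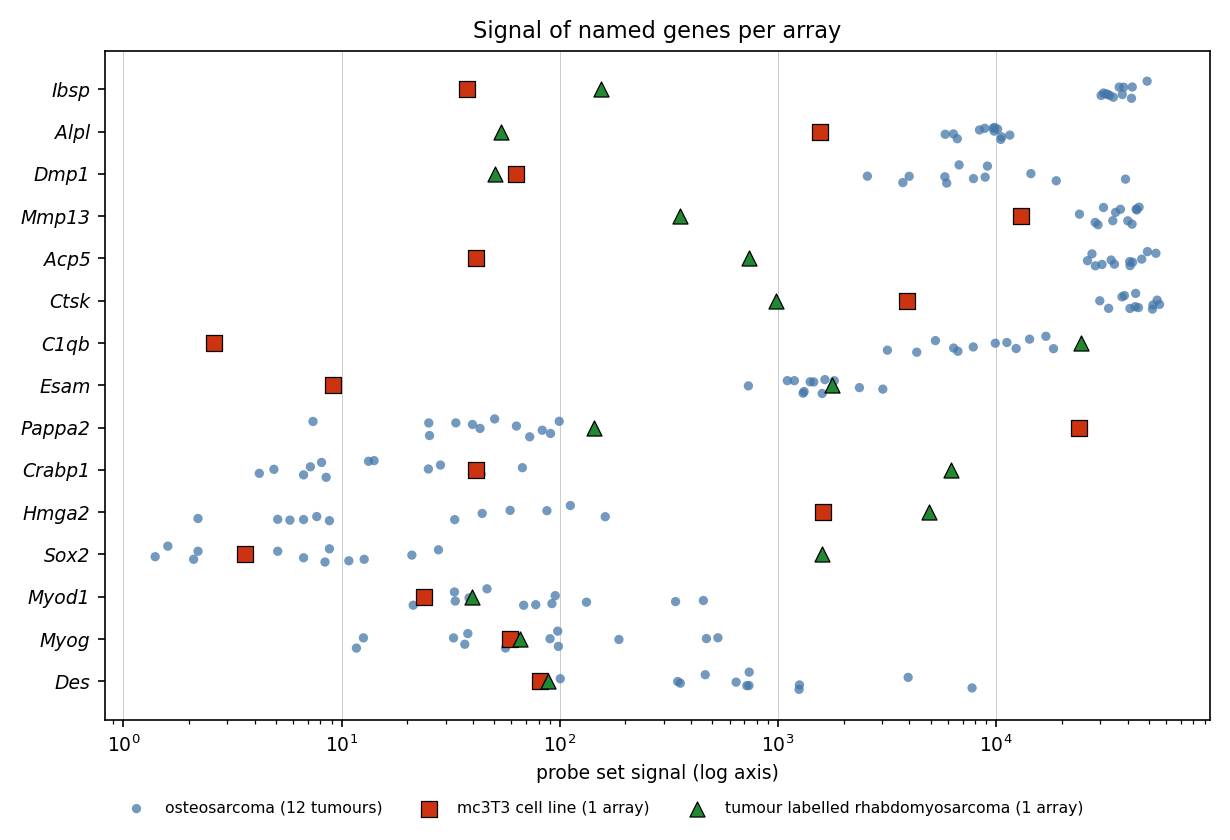
Signal of 15 named genes on each array (horizontal log axis, array signal units; signals below 1 are drawn at 1). Dots are the 12 osteosarcomas, squares mc3T3 and triangles the tumour labelled rhabdomyosarcoma; Ibsp lay between 30210.3 and 49087 in the osteosarcomas, against 37.4 in mc3T3 and 155 in the tumour labelled rhabdomyosarcoma.

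In all, 141 genes rose and 208 fell in the tumour labelled rhabdomyosarcoma (limma, two-sided), with 204 and 260 probe sets. Genes called higher and lower, adjusted over the list alone, were 0 and 15 for osteoblast, 0 and 16 for osteoclast, 7 and 0 for MHC class II, 2 and 0 for interferon, 5 and 0 for T and NK cell, 0 and 2 for adipocyte, 0 and 1 for myogenic, 2 and 2 for cartilage, 1 and 1 for chromosome 9 region, 0 and 3 for fibroblast and 2 and 0 for osteosarcoma and p53 pathway genes, and 0 and 0 for the other 12 lists. As this group holds a single array, the test assumes that it would vary as an osteosarcoma does. The share of called genes that were higher was 40.4%, against 30.1% with a pseudocount of 10 and 54.6% with a pseudocount of 100, and with a pseudocount of 10 the count of probe sets called higher was 132.

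Between the tumour labelled rhabdomyosarcoma and mc3T3, with 1 array each, there is no replicate check and no p-value. The genes of the random lists were drawn independently. Genes of a real list can vary together, with an estimated correlation from 0.0104 (osteosarcoma and p53 pathway) to 0.848 (mature skeletal muscle). The percentiles may therefore overstate how far a list stands out. The macrophage and monocyte genes were a median of 6.92 higher on the log2 scale, the MHC class II presentation genes 6.42, the endothelial genes 3.02 and the interferon response genes 1.82, each at the percentile 100 of random lists of its size matched on mean expression. T and NK cell genes were a median of 2.67 higher (percentile 99.97), mature skeletal muscle genes 1.07 (percentile 99.98) and osteoclast genes 0.79 (percentile 99.93). The contractile and adherent-culture genes (-1.33, percentile 0) and the osteoblast genes (-1.31, percentile 0) were lower, as were cholesterol synthesis (-1.03, percentile 0.01) and p53 target genes (-0.65, percentile 0.11). The myogenic regulators and embryonic muscle genes had a median difference of 0.47 (percentile 92.0), and the cell cycle and mitosis genes 0.09 (percentile 70.0). The medians of the others were 1.66 for B and plasma cell (percentile 98.5), 0.89 for adipocyte (98.6), 0.66 for erythroid (81.7), 0.40 for hypoxia and glycolysis (94.8), 0.22 for neutrophil (71.7), 0.18 for chromosome 9 region (73.0), 0.13 for osteosarcoma and p53 pathway (71.1), -0.33 for fibroblast (8.01), -0.65 for keratinocyte (8.92) and -0.75 for cartilage genes (1.53).

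Among the 12 osteosarcomas, skeletal muscle genes varied most. The fast myosin gene Myh4 had the largest SD, 3.43 on the log2 scale, with signals from 23.1 to 43807. It was followed by the troponin genes Tnnt3 (SD 3.16) and Tnni2 (3.02), Mybpc2 (3.09) and Acta1 (2.97). The muscle creatine kinase Ckm (2.83), Pvalb (2.78), Rps4l (2.76), Tnnc2 (2.73) and Myl1 (2.73) came next. Of these 10 genes, 9 belong to the mature skeletal muscle list, as do 15 of the 30 most variable genes. The mean level of that list was 13.27 in osteosarcoma 6 and 12.27 in osteosarcoma 9, and 6.42 to 10.38 in the other 10. Over all genes the median SD was 0.43, and 840 genes had an SD above 1. No test was made of this variation.

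A list of neighbouring genes on chromosome 9, a region known to be amplified in some mouse osteosarcomas, was examined across the tumours. Osteosarcomas 1 and 2 had the highest signals for most of these genes. Yap1, the transcriptional coactivator of the Hippo pathway, had signals of 20804 and 17439.8 in osteosarcomas 1 and 2, against 1448 to 2732 in the other 10 (9.90 and 8.30 times their median). Birc2, an inhibitor of apoptosis, had 6552 and 4171 against 561 to 1463. Birc3, its neighbour and relative, had 7490.4 and 4705 against 904 to 3335, and Dcun1d5 had 23274 and 18538 against 1787 to 4492. The inflammatory caspase gene Casp12 had 12605 and 4272 against 220.1 to 1645. Mmp13 was high in every osteosarcoma, with 41874 and 45100.2 against 24035 to 44011, and Arhgap42, farther along, had 757 and 690.2 against 374 to 1109. Of 19 measured members of the list, 12 in osteosarcoma 1, 12 in osteosarcoma 2 and 11 in both lay above all of the other 10 tumours.

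The values of these 2 tumours stand apart, so correlations over all 12 tumours are set beside those without them. Over all 12 tumours, 11 of 18 members correlated with Birc2 by r at an adjusted permutation p under 0.05, and 4 by rho (Birc3, Yap1, Casp1 and Casp12). Without osteosarcomas 1 and 2, the tumours farthest from the median of Birc2, 2 did by r and 0 by rho. The 2 were Birc3 (r = 0.813, permutation p = 0.00209, adjusted p = 0.0312; rho = 0.770, p = 0.0127, adjusted p = 0.114; n = 10) and Casp12 (r = 0.802, permutation p = 0.00347, adjusted p = 0.0312; rho = 0.770, p = 0.0123, adjusted p = 0.114; n = 10). Of the 9 calls lost, Mmp13 (r = 0.621 before and 0.634 after) kept its r, Casp1 (0.707), Yap1 (0.674), Casp4 (0.597) and Pdgfd (0.586) kept part of it, and Dcun1d5 (0.368), Tmem123 (0.313), Dync2h1 (0.269) and Mmp7 (-0.379) fell furthest. Within the 6 tumours whose identifiers start with m, neither passed in exact permutation tests (Birc3 r = 0.510, adjusted p = 0.721; Casp12 r = 0.882, adjusted p = 0.400).

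**Figure D3:**
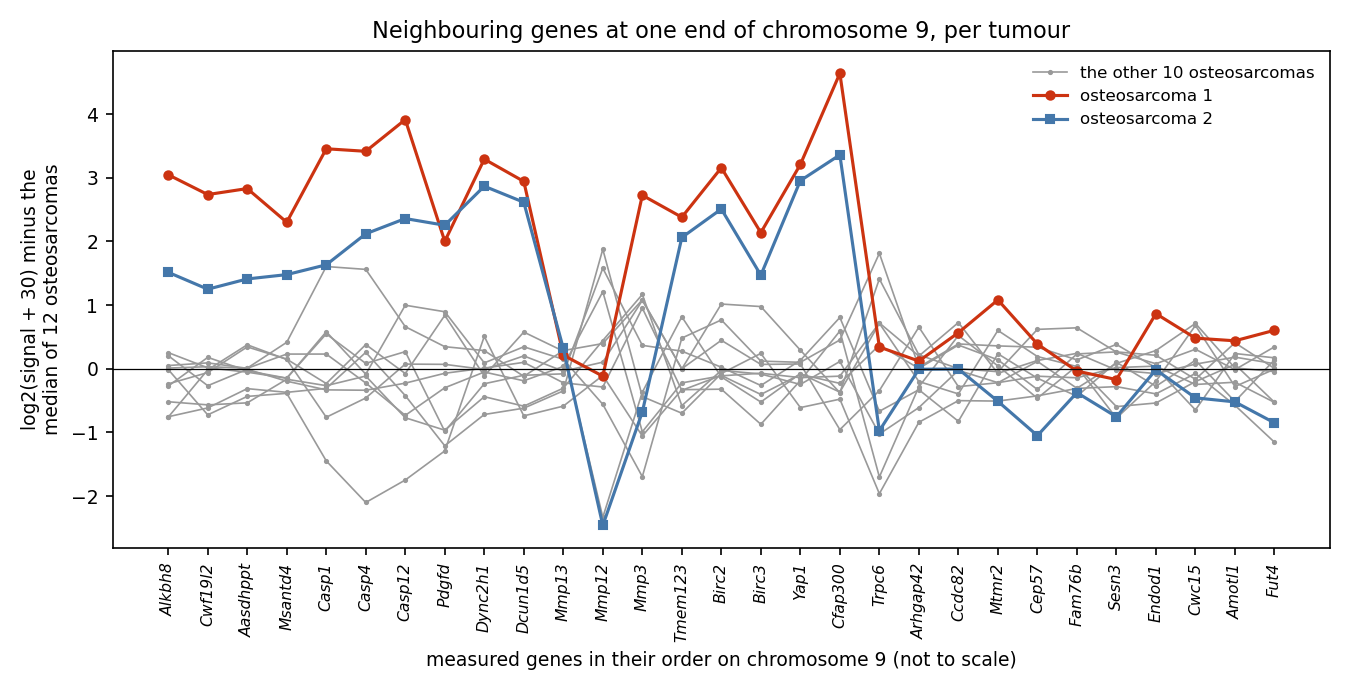
Measured genes at an end of chromosome 9 in their order along it (horizontal axis, not to scale), with log2(signal + 30) of each tumour minus the median of the 12 osteosarcomas (vertical axis, log2 units). Red circles are osteosarcoma 1, blue squares osteosarcoma 2 and grey dots the other 10; Yap1 stood at 20804 and 17439.8 signal units in the 2 coloured tumours and at 1448 to 2732 in the other 10.

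Of 5 relations tested between list levels across the 12 osteosarcomas, that of the T and NK cell list with the interferon response list passed (r = 0.842, permutation p = 0.00025, adjusted p = 0.00125; rho = 0.881, permutation p = 0.00041, adjusted p = 0.00205). The T and NK cell level was low, at 5.999 to 7.767 in the osteosarcomas against 6.278 in mc3T3. Osteosarcomas 7 (6.25), 11 (5.999) and 12 (6.103) lay below mc3T3, and the other osteosarcomas above it. With no detection calls, the T and NK cell signal of these low tumours could not be told from background. The relation was not tested with them left out together. Without the 2 tumours farthest from the median of the T and NK cell list the relation still passed (r = 0.807, adjusted p = 0.0247, n = 10). Within the 6 tumours whose identifiers start with m it did not (r = 0.804, exact p = 0.0458, adjusted p = 0.229; rho = 0.771, exact p = 0.103). The osteoblast list did not pass with the cell cycle list (r = -0.415, p = 0.201, adjusted p = 0.449; rho = -0.273, p = 0.387). It did not with the osteoclast list (r = -0.137, p = 0.675, adjusted p = 0.675; rho = 0.0420, p = 0.904). Nor did it with the cartilage list (r = 0.194, p = 0.536, adjusted p = 0.670; rho = 0.483, p = 0.116). The osteoclast list did not pass with the macrophage list (r = -0.345, p = 0.270, adjusted p = 0.449; rho = -0.266, p = 0.402). These p-values are from two-sided permutation tests. Without the 2 farthest tumours r was 0.0291 for osteoclast with macrophage, -0.545 for osteoblast with cell cycle, 0.397 for osteoblast with osteoclast and -0.0267 for osteoblast with cartilage levels, with no adjusted p under 0.05.

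The letter that starts a tumour's identifier, whose meaning the labels do not give, was examined as a possible batch. Between the 6 tumours with m and the 4 with c, 3 genes were called higher and 0 lower (limma; 852 genes at an unadjusted p under 0.05). They were Rpgrip1, a gene of the photoreceptor cilium (4.96, adjusted p = 0.00601), Ngdn (1.86, adjusted p = 0.0186) and Tmem267 (2.02, adjusted p = 0.0408), named after their values were seen.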

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

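The rule that set control probe sets against the mc3T3 array was chosen after their values had been seen, and no test was made here. Control probe sets, which no comparison used, include 3 for the mouse transferrin receptor, the carrier of iron uptake, and these were above the mc3T3 array in all 12 osteosarcomas. The probe set at the 3' end of the transcript had a mean signal of 898 in the osteosarcomas (272 to 1519) against 92.6 in mc3T3. The probe set at the 5' end had 214 (61.1 to 480.1) against 9.3, and the middle probe set 213 (59.7 to 481) against 9.8. The gene's own probe set, Tfrc, had 3118 to 11690 in the osteosarcomas, 1027 in mc3T3 and 1595 in the tumour labelled rhabdomyosarcoma. The rule looked for increases only. All control probe sets of beta-actin and pyruvate carboxylase lay below mc3T3 in all 12 osteosarcomas. At the 3' end these had 37452 to 55825 against 68509 for beta-actin and 77.3 to 194 against 750 for pyruvate carboxylase.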

How the results depend on the processing

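Leaving out osteosarcomas 6 and 9 together was added after the data had been seen; the other alternatives were fixed before the data were examined. With an estimated correlation in camera, 0 lists passed for osteosarcoma against mc3T3 in place of 10, and 1 in place of 9 for the tumour labelled rhabdomyosarcoma; by construction this setting allows for the correlation of a list's genes. The most genes called for a lone osteosarcoma was 22 with quantile normalization in place of 59; the cause was not tested. With a pseudocount of 10, 132 probe sets were higher in the tumour labelled rhabdomyosarcoma in place of 204; the cause was not tested. Without the 2 tumours farthest from the median of Birc2, 2 chromosome 9 genes passed in place of 11.

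Leaving out each osteosarcoma in turn gave 936 to 1104 genes higher and 486 to 603 lower against mc3T3 (1432 to 1681 and 785 to 1040 probe sets), and 128 to 151 higher and 172 to 233 lower in the tumour labelled rhabdomyosarcoma (183 to 218 and 210 to 302 probe sets). The lists that passed were 10 to 12 and 9 to 13, and the chromosome 9 genes 9 to 11. For list levels, r was 0.792 to 0.876 for T and NK cell with interferon, -0.559 to -0.203 for osteoclast with macrophage, -0.537 to -0.221 for osteoblast with cell cycle, -0.336 to 0.150 for osteoblast with osteoclast and 0.0823 to 0.285 for osteoblast with cartilage. Without osteosarcomas 6 and 9, 891 and 453 genes were called against mc3T3 and 133 and 155 for the tumour labelled rhabdomyosarcoma, with 11 and 9 lists.

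Of 260 gene results that the rule for named genes allows, 22 crossed the adjusted p of 0.05 (limma) under at least 1 alternative (15 lost, 7 gained). The minimum change of 1 was not applied in this count. Of the results under 0.05 with the main settings, 0 reversed their sign. The p53 target list did not pass against mc3T3 (adjusted p = 0.0543; adjusted p = 0.221 with an estimated correlation). At the preset correlation it passed as lower without osteosarcoma 2 (adjusted p = 0.0488), 5 (0.0498), 6 (0.0414), 9 (0.0480), 10 (0.04997) or 12 (0.0468), and its range over 19 alternatives was 0.0187 to 0.0695. In the tumour labelled rhabdomyosarcoma, the myogenic list passed as lower without osteosarcoma 1 (0.0454), 4 (0.0348), 7 (0.0343), 8 (0.0493), 10 (0.0392) or 11 (0.0272), with a range of 0.0272 to 0.0753, but it had adjusted p = 0.7 with an estimated correlation. Leaving out osteosarcoma 8 also let its cartilage, hypoxia and cell cycle lists pass (0.0493 each), leaving out osteosarcoma 3 its cell cycle list (0.0413), and leaving out osteosarcoma 5 the chromosome 9 list against mc3T3 (0.0498). With an estimated correlation none of these lists passed over all 12 osteosarcomas. The myogenic list against mc3T3 did not pass with a signal minimum of 500 (0.0505). Using the deposited values without rescaling moved nothing, since the arrays had already been scaled, and says nothing about stability. An intensity trend, the mean of probe sets and the m tumours alone were run for gene calls and not for lists. No paired analysis was possible because the labels give no replicate numbers and 2 of the groups hold 1 array each. With no detection calls, low signals are limited by an unknown background.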

Other observations

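The array-wide median, the share of shared high genes in the run and the other splits by identifier letter were tests written before their results were seen; all other tests here, the share in the part common to both runs and the intervals of the shares included, were chosen after the result was seen. In osteosarcoma 7 a run of 17 neighbouring genes on chromosome 3, from Rpf1 to Fpgt, was high, and 13 of them lay above all of the other 11 osteosarcomas, with a median of 2.61 times the others' median (0.634 to 3.81). The chaperone gene Dnajb4 had a signal of 6667 against 1119 to 2794, the fatty acid dehydrogenase gene Acadm 7998 against 2201 to 3839, and the protein kinase A subunit gene Prkacb 5808 against 1692 to 2759.9. Osteosarcoma 12 had a cell cycle and mitosis level of 8.997, against 10.20 to 10.67 in the other 11. Its array also had the highest beta-actin ratio of the osteosarcomas (2.13), the lowest median signal (67.1) and the lowest share of probe sets at 200 (33.8%). Osteosarcoma 6 had a neutrophil and granulocyte level of 11.37 and an erythroid level of 9.87, against 7.15 to 10.04 and 6.12 to 7.49 in the other 11.

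Xist, the RNA of the inactive X chromosome, had a signal of 112 in osteosarcoma 6, 55.3 in the tumour labelled rhabdomyosarcoma and 90 in mc3T3, against 1312 to 9250 in the other 11 osteosarcomas. The Y-linked gene Eif2s3y had 541, 393 and 1327 in these 3 arrays and 1.8 to 54.9 in the other osteosarcomas, and Kdm5d, also Y-linked, 179, 124 and 1613 against 2.9 to 42.1. Uty, a further Y-linked gene, did not set osteosarcoma 6 apart, with 32 against 5.2 to 50.5 in the other osteosarcomas, and had 74.5 in the tumour labelled rhabdomyosarcoma and 396 in mc3T3. The labels do not give the sex of the animals. Mast cell genes were high in the tumour labelled rhabdomyosarcoma, with signals of 1804 for Cpa3, 1647 for Cma1, 958 for Mcpt4 and 615 for Tpsb2. In the osteosarcomas they reached at most 456, 352, 309 and 160.2, all in osteosarcoma 9. These genes were picked after their values were seen, and no test was made.

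Neighbouring genes high in osteosarcomas 1 and 2 lay in runs of 14 genes on chromosome 9 in the former, from Casp4 to Trpc6, and of 10 genes in the latter, from Casp4 to Birc2, of which 8 in each tumour lay above all of the other 10 (median 7.98 times their median, 0.746 to 17.3, and 5.17 times, 0.0547 to 8.06; not Mmp12 in either, Mmp13 in osteosarcoma 1 or Mmp3 in osteosarcoma 2). The window rule sets these ends, and past them Yap1 (2.95) and Cfap300 (3.36) were high in osteosarcoma 2 too, as were the 5 genes from Alkbh8 to Casp1 in both (2.30 to 3.46 and 1.25 to 1.63). Alkbh8 is the first scanned gene of chromosome 9, and Casp4 the first that can be the centre of a window. Both runs thus lie at a chromosome end, where earlier settings of the scan had given spurious runs. In the scaled values the median over all genes lay 0.0058 and 0.0313 from the median osteosarcoma on the log2 scale. No array-wide shift was thus left in them that could raise these genes. Scaling every array to 1 trimmed mean largely fixes that median, so it is no separate test of an array-wide difference. Another cell type as the whole source stays open. Of the 14 genes at least 2 higher in both tumours, 9 lay in the run of osteosarcoma 1 (64.3%, exact 95% interval 35.1 to 87.2). In the part common to both runs lay 7 (50%, 23.0 to 77.0), and Adam23, Col4a5, Ct55, Ms4a4d and Ndufa4l2 lay in neither. These shares were above the 20% at most that this explanation needed, though both intervals hold the preset 50%. They cannot decide, because the run was picked from the same values and the intervals treat neighbouring genes as independent. Gain of a block of neighbouring genes is a candidate explanation that stays open: 0 of 100 shuffles of the gene order gave a run as long in either tumour, and 0 of 100 in osteosarcoma 7 for its chromosome 3 run. The shuffles treat neighbours as independent, so genes regulated together may pass too. In osteosarcoma 4 a run of 8 genes on chromosome 1 from Cfap45 to Ifi202b, near a family of interferon-inducible genes, was also matched by 0 of 100. The source of that run was not tested. Copy number was not analysed here, and no biological explanation was tested.

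The tumour labelled rhabdomyosarcoma did not show higher Myod1, Myog or Des signals than the osteosarcomas. A label exchanged with an osteosarcoma of the series was argued against, since every osteosarcoma had at least 108 times its Ibsp and Alpl signals, while a single wrong label or an exchange with an outside sample stays open. Degraded RNA on that array was argued against, since its beta-actin ratio of 1.24 lay below the osteosarcomas (1.42 to 2.13). Tumour cells diluted by immune cells cannot be told apart from tumour cells with low muscle regulators: the macrophage and monocyte level of 13.09 lay above the highest osteosarcoma (12.65), and while Myod1, Myog, Des and Cdh15 differed from mc3T3 by a median of 0.10 on the log2 scale, the mature muscle genes were a median of 1.07 above it, and no value here gives the share of tumour cells. No biological explanation was tested.

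Skeletal muscle tissue within some tumour samples may account for the variation of muscle genes among the osteosarcomas: the 28 mature muscle genes had a median pairwise correlation of 0.874 over the 12 tumours and 0.782 without osteosarcomas 6 and 9, with Myh4 at 43807 in osteosarcoma 6 and 28724 in osteosarcoma 9. Muscle differentiation of tumour cells without mature muscle cannot be told apart from this over the 12 tumours. Osteosarcomas 6 and 9 did hold mature muscle signal, with mean levels of 13.27 and 12.27 against 6.28 in mc3T3. They were singled out by that same level, so it cannot serve as a test of this explanation. Over the 12 tumours Myod1 (r = 0.823, permutation p = 0.00177, adjusted p = 0.00177; rho = 0.678, p = 0.0183) and Myog (r = 0.901, permutation p = 0.0002, adjusted p = 0.0004; rho = 0.811, p = 0.00208) went with the mature muscle level. Without osteosarcomas 6 and 9 r was 0.455 for Myod1 (p = 0.184; rho = 0.455, p = 0.192) and 0.721 for Myog (p = 0.0202, adjusted p = 0.0403; rho = 0.685, p = 0.0352, adjusted p = 0.0705), so that Myod1 no longer passed and Myog passed in r but not in rho after adjustment, while within the 6 m tumours, which hold both, r was 0.965 and 0.957 (exact p = 0.0111 and 0.00972). Tumour cells that form mature muscle themselves stay open, and the labels name no dissection or sort that would remove muscle. No biological explanation was tested.

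For the identifier letters, 2 of 100 splits of the 10 tumours into 6 and 4, the real split included, gave as many as its 3 genes. That share is under 0.05, but the highest other split gave 6. The real split gave 2 genes with quantile normalization and 2 with a pseudocount of 100, where no other splits were run. Chance is therefore not excluded. The gene that led this list, Rpgrip1, had signals of 529, 77.4, 109.5 and 62.4 in the 4 tumours with c (osteosarcomas 1, 2, 7 and 11) and 3161 to 10630 in the other 8.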
